A study of Rattus norvegicus with 6 samples.

How the data were processed

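Bulk RNA sequencing was run on 6 rat liver samples, 3 after embolization with blank microspheres (GM) and 3 after embolization with zinc sulfide microspheres (GZM), grouped and numbered by their titles and descriptions. Per the labels' protocols, RNA was extracted with TRIzol, enriched for polyadenylated transcripts, made into strand-specific libraries with dUTP and sequenced as paired-end reads. The aligner and the read counter are not given in the sources used here, nor whether counting used the strand. Overlapping and antisense genes and near-identical family members (P450, MHC, Mup, hemoglobin, metallothionein and Mage genes among them) are therefore uncertain. Per the submitters' processing notes the genome build is mRatBN 7.2, but positions in the deposited table reach 282724300 on chromosome 1, beyond that build, and some gene names follow an earlier annotation.

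The deposited table holds 32623 genes with Ensembl identifiers, symbols, exon lengths and, per the file headers, a count and an FPKM value for each sample. The deposited counts are whole numbers, not normalized. The deposited FPKM values are the counts divided by exon length and by the sample's own summed counts, with no other scaling: recomputing them from the counts gave all 195738 values within 0.01. The exon length column, per the file headers, is a size in bases and was used for that check and for a test of length bias. The columns for the GZM samples carry the letters in another order (ZGM) and were matched by these letters and their numbers. All per-sample columns were used.

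The main test, fixed before the data were examined for the case that the table held counts, was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts with TMM factors and edgeR's default low-count filter, no covariate and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is the one implied by its quasi-F value. CPM values are TMM-scaled. TMM factors were 1.43, 1.42 and 1.17 for GM 1 to 3 and 0.742, 0.715 and 0.793 for GZM 1 to 3. Total counts ran from 13443115 to 16604067 per sample. A group with 0 counts was given a floor of 3 counts over its summed library size, and a group with 1 to 3 counts an exact 95% binomial counting interval.

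Gene lists, 53 in number, were fixed before the data were examined. They cover energy and liver metabolism, hypoxia, vessels, zinc and sulfide handling, interferon and stress responses, cell death, cell division, and markers of the cell types a piece of liver can hold. The lists hold 983 entries (926 different symbols), of which 44 entries were not matched in the table. Lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) on log2 CPM with a prior count of 2, adjusted over lists, and again with the correlation estimated and with fry. Genes named in the text follow a rule fixed at the same time: the 12 largest rises and 12 largest falls among symbol-named genes that passed with groups not overlapping, 17 genes chosen for the study's subject, and up to 4 genes of smallest p from each list. A gene outside the rule is said to have been named after its values were seen.

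Counts were simulated for the 14298 genes of the GZM against GM comparison, with 200 genes changed. They used the data's pooled means, TMM-scaled library sizes and dispersions. There edgeR recovered 22% of 2-fold and 85% of 4-fold changes with 3 false calls, limma on FPKM 11% and 80% with 3, and DESeq2 43% and 92% with 37. The simulated groups had no difference in composition. In the data 6285 genes changed, and limma on FPKM moved the median log2 fold change by -0.74. These rates, and limma's 3 false calls above all, therefore do not describe the real data.

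The alternatives were edgeR without the low-count filter or with the replicate number as a block, leaving out each library, a 2-fold minimum, DESeq2 1.42.0 and limma on log2 FPKM with pseudocounts 0.1 and 0.5, no filter or a mean of at least 1, median-of-ratios or quantile scaling, the block, sample quality weights, and other variance priors. Added after seeing the data were limma on log2(FPKM + 1), edgeR with library totals, edgeR with median-of-ratios factors, and edgeR without GM 3 and GZM 1. Figures were drawn with matplotlib 3.10.9.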

Results

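The series measured messenger RNA in rat liver tissue by bulk RNA sequencing of 6 libraries. Of these, 3 (GM) come from the group embolized with blank microspheres, the control, and 3 (GZM) from the group embolized with zinc sulfide microspheres. Embolization blocks the vessels that feed a tissue, and the study's title places the work in hepatocellular carcinoma. The labels call all 6 samples liver and do not say whether a piece held tumour, surrounding liver or both. Gene counts summed to 14552885, 16578929 and 16604067 in GM 1, 2 and 3, and to 13443115, 14843721 and 16073943 in GZM 1, 2 and 3. Counts of every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 10.6 for the closest pair (GZM 2 and GZM 3) and 215 for the most distant (GM 2 and GM 3), so each library was counted as 1 sample. The labels number the samples of a group as replicate biosamples and do not say that these are separate animals, so p-values may measure only the spread between these samples.

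The comparison asks how liver tissue after embolization with zinc sulfide microspheres differed from tissue after embolization with blank ones. Genes of hepatocyte function were higher in GZM and genes of cell division were lower. Transcripts of the fixed hepatocyte list made up 16.2% ± 0.422 of all counts in GZM and 5.64% ± 3.42 in GM (SD, n = 3 each), with GM 3 at 9.52% and the other GM libraries at 4.33% and 3.07%. The 10 most abundant genes of each library took 22.5% ± 1.09 of counts in GZM and 10.1% ± 2.83 in GM. On the first principal component, which held 76.9% of the variance, the GZM libraries lay between 66.4 and 74.7 and the GM libraries at -75.3, -101.1 and -34.9, GM 3 being the GM library nearest to GZM.

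**Figure D1:**
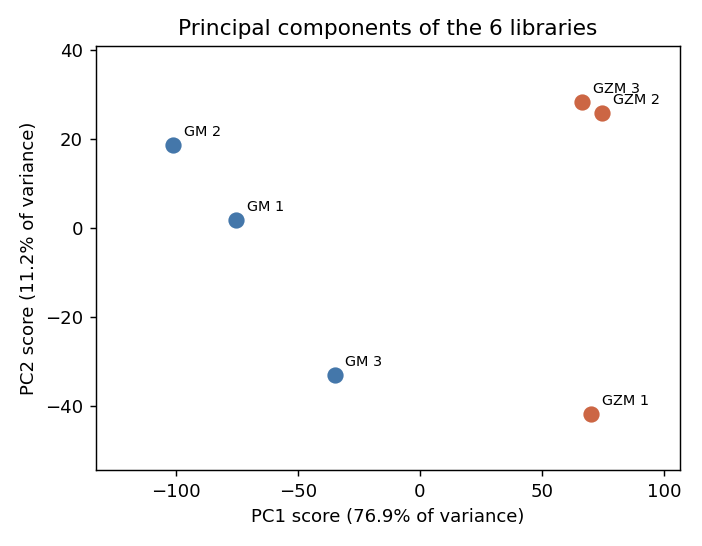
Scores of the 6 libraries on the first 2 principal components of log2 CPM (TMM-scaled), 1 point per library, with GM in blue and GZM in orange and the share of variance on each axis. The groups separate on the first component, where GM 3 scores -34.9 against -75.3 and -101.1 for the other GM libraries, and GZM 1 stands apart from GZM 2 and GZM 3 on the second.

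In all, 6285 of 14298 tested genes changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 3181 higher and 3104 lower in GZM, and 4142 of them by at least 2-fold (2061 higher, 2081 lower). At an unadjusted p under 0.05 the number was 7496. The GZM and GM libraries did not overlap for 8307 genes, or 58.1%, where chance gives 10% for 3 against 3. The balance of directions depends on the scaling. With library totals in place of TMM factors, 9828 genes changed, 1315 higher and 8513 lower, because the median fold change of all genes then moved by -0.84 on the log2 scale. Fold changes below are relative to the TMM scale, and directions that turn on the other scale are named. Leaving out GZM 2 lowered the count to 3777.

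Glucose-handling genes moved in opposite directions along the pathway. Hexokinase 2 (Hk2, ENSRNOG00000006116, chromosome 4, 113559427 to 113610243), which traps glucose in the cell and is typical of tumour and fetal tissue, was 3.74-fold lower in GZM, at 37.9 ± 1.97 CPM against 141.5 ± 10.5 (SD, n = 3 each; log2 fold change -1.90 ± 0.15 SE, edgeR adjusted p = 0.00164). Hexokinase 1 (Hk1) fell by 1.67 on the log2 scale, the glucose transporter Slc2a1 by 1.72, and Pkm, the pyruvate kinase of most tissues other than liver, by 1.95. Of 23 tested glycolysis genes 14 fell and 1 rose, and adjusted over the list alone 16 fell and 2 rose. The single riser over all genes was Pklr, the liver form of pyruvate kinase, at a log2 fold change of 1.53, named after its values were seen. The list was called lower by camera (adjusted p = 0.000483, median -0.93), a call not kept with its correlation estimated (adjusted p = 0.48 with an estimated correlation). Lactate dehydrogenase A (Ldha) did not pass (log2 fold change 0.61 ± 0.22 SE, adjusted p = 0.0547) and turned to -0.23 with library totals. Ldhb (-0.93 ± 0.45, adjusted p = 0.128) did not pass in the main test. It passed as lower in 13 of 23 other settings, most of them scaled to library totals (-1.80 in edgeR, adjusted p = 0.0108). That scale moved the median of all genes by -0.84 in edgeR, so these settings are not separate support. With TMM factors it passed without GZM 1 (-1.57, adjusted p = 0.0173) and with the replicate block (-1.03, adjusted p = 0.0396). Without both GM 3 and GZM 1 it also passed (-1.73, adjusted p = 0.0014). In the gluconeogenesis list 8 of 11 genes rose and 1 fell (8 and 1 adjusted over the list alone; median 2.25; camera adjusted p = 0.000502, and adjusted p = 0.48 with an estimated correlation). Phosphoenolpyruvate carboxykinase (Pck1), which commits carbon to glucose synthesis, rose by 4.33, tyrosine aminotransferase (Tat) by 3.49 and fructose bisphosphatase (Fbp1) by 3.26, while the mitochondrial form Pck2 (-0.58), named after its values were seen, was the single gene that fell. Pck2 lost its call without any 1 library other than GM 3 (adjusted p from 0.0555 to 0.124).

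The fixed list of hypoxia targets was not called as a group. Hif1a (ENSRNOG00000008292), the oxygen-regulated transcription factor subunit, was 2.78-fold lower in GZM, at 89.7 ± 11.8 CPM against 249.7 ± 9.32 (log2 fold change -1.48 ± 0.17 SE, adjusted p = 0.00215). The vessel growth factor gene Vegfa was 2.15-fold higher (1.11 ± 0.21, adjusted p = 0.00587), but only 0.28 with library totals, where it did not pass (adjusted p = 0.2). Of 25 tested targets of hypoxia-inducible factor 1, 9 fell and 3 rose (9 and 5 adjusted over the list alone), with a median of -0.53 and camera adjusted p = 0.205. Ndrg1, a stress-induced target, fell by 1.81 and the collagen hydroxylase subunit gene P4ha1 by 1.01. Across 20 angiogenesis and endothelial genes 4 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.413, median 0.31, turning to -0.52 with library totals). Egfl7 rose by 1.24 (adjusted p = 0.129 with library totals) and the VEGF receptor gene Flt1 fell by 0.83. Angpt2, which loosens vessel walls, fell by 1.33, a call lost without GM 1 (adjusted p = 0.0513) or GZM 2 (0.0616). The lymphatic and sinusoidal receptor gene Flt4 rose by 1.31, a call lost without GM 1 (0.068), GZM 1 (0.0612), GZM 2 (0.0619) or GZM 3 (0.0537).

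**Figure D2:**
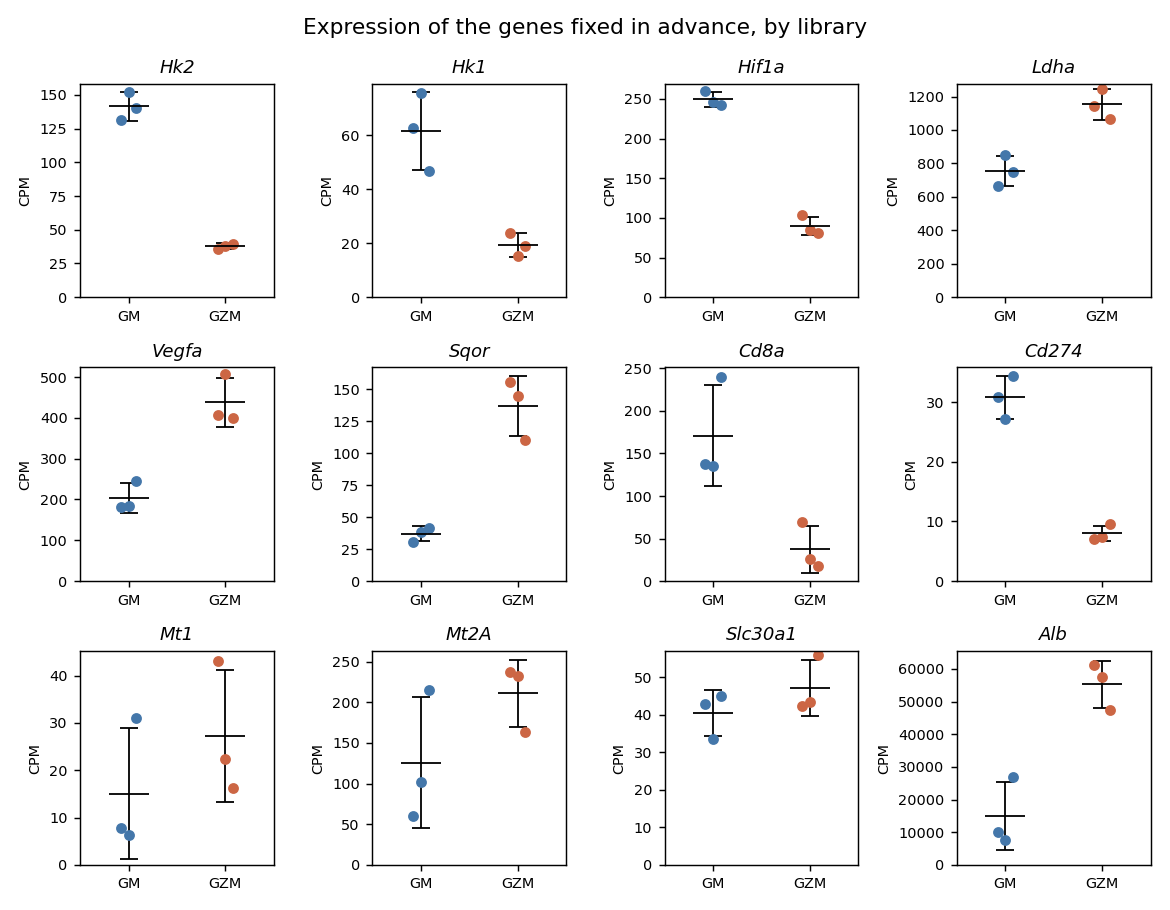
CPM (TMM-scaled) of 12 of the genes fixed in advance, 1 point per library, with the group mean as the wide bar and error bars of 1 SD (n = 3 per group); every axis starts at 0. Hk2, Hk1, Hif1a, Cd8a and Cd274 lie lower in all 3 GZM libraries than in any GM library, Vegfa, Sqor and Alb lie higher, and Mt1, Mt2A and Slc30a1 overlap; Ldha does not overlap here but turns to a log2 fold change of -0.23 with library totals.

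Genes of sulfide handling were higher in GZM. Sqor (ENSRNOG00000000172, chromosome 3, 114900343 to 114939370), the mitochondrial quinone oxidoreductase that oxidizes hydrogen sulfide, was 3.71-fold higher, at 136.7 ± 23.6 CPM against 36.9 ± 5.82 (SD, n = 3 each; log2 fold change 1.89 ± 0.20 SE, adjusted p = 0.00192). Mpst, which makes hydrogen sulfide from mercaptopyruvate, rose by 1.74, and sulfite oxidase (Suox) by 2.13. In the whole list 9 of 10 tested genes rose, also 9 adjusted over the list alone, with a median of 2.04 (camera adjusted p = 6.83e-05, and adjusted p = 0.525 with an estimated correlation). With library totals the list median was 1.26. The list's level, as mean log2 CPM relative to the mean of the 6 libraries, followed that of the hepatocyte list: -1.13, -1.39 and -0.25 in GM 1, 2 and 3 and 1.10, 1.01 and 0.66 in GZM 1, 2 and 3 for sulfide genes, against -1.61, -2.11, -0.27, 1.41, 1.45 and 1.13 for hepatocyte genes.

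For zinc-responsive genes the outcome depended on the libraries and the test used. The metallothionein genes Mt1 (0.86 ± 0.63 SE, adjusted p = 0.298) and Mt2A (0.75 ± 0.43, adjusted p = 0.189; -0.03 with library totals), which bind zinc and are induced by it, did not pass with all 6 libraries. Both passed as higher in 3 of 23 other settings. The first was without GM 3, the GM library with the most counts of each (Mt1 1.98, adjusted p = 0.00518, and Mt2A 1.42, adjusted p = 0.00369). The others were without both GM 3 and GZM 1, and limma with sample quality weights, whose estimation stopped before converging. All of them drop or reweight libraries, so they are not separate support for a rise. The gene labelled Mt1 lies on chromosome 17 (78793336 to 78793724), and Mt2A lies on chromosome 19. Whether the one labelled Mt1 is the zinc-induced gene or a near-identical copy was not settled. The zinc exporter gene Slc30a1 did not pass either (0.22 ± 0.18, adjusted p = 0.342) and turned to -0.60 with library totals (adjusted p = 0.0285). Of 14 tested genes of zinc response and transport 6 rose and 2 fell, with the same numbers adjusted over the list alone, and camera made no call (adjusted p = 0.192; median 0.61, turning to -0.23 with library totals). Fry called the list higher (adjusted p = 0.0181). Among zinc importers, Slc39a4 rose by 2.79 and Slc39a14 by 1.77, while Slc39a6 fell by 1.58 and Slc39a10 also fell by 1.58.

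Hepatocyte genes rose nearly throughout. In the hepatocyte list 23 of 24 tested genes rose (23 adjusted over the list alone), with a median log2 fold change of 2.44 and camera adjusted p = 4.43e-09. Hnf4a, the transcription factor that maintains hepatocyte identity, rose by 2.57 and transthyretin (Ttr) by 2.39. Albumin (Alb), the main secreted protein of hepatocytes, was 3.70-fold higher (1.89 ± 0.63 SE, adjusted p = 0.0413), a call lost on leaving out GM 1 (adjusted p = 0.169), GM 2 (0.114), GZM 1 (0.0819), GZM 2 (0.104) or GZM 3 (0.0892). The fetal albumin relative Afp, at 16.9 ± 6.30 CPM in GZM and 2.38 ± 0.977 in GM, rose by 2.83 (adjusted p = 0.00253). Cytochrome P450 and drug metabolism genes had the highest median, 2.92 with 18 of 19 genes higher, led by Cyp4a2 (4.43) and Cyp2c11 (3.71). All 22 fatty acid oxidation and ketogenesis genes rose (median 1.87; Cpt2 by 2.37, Acadm by 2.47), as did 20 of 21 cholesterol synthesis genes (median 1.47; Insig1 by 2.90, Dhcr7 by 2.17). Urea cycle and amino acid catabolism genes rose in 18 of 19 cases (median 2.23; Asl by 2.90), complement and coagulation genes in 20 of 22 (median 2.34; Serpinc1 by 2.66), and bile acid synthesis and transport genes in 12 of 16 (median 2.17; Abcb11 by 3.17). Adjusted over the list alone the numbers higher were 18 for P450, 22 for fatty acid oxidation, 21 for cholesterol, 18 for the urea cycle, 20 for complement and 13 for bile acid genes. Camera called all of these lists, at adjusted p between 4.95e-12 (fatty acid oxidation) and 2.58e-05 (bile acids). None was kept with its correlation estimated, where the hepatocyte list, fatty acid oxidation, urea cycle, complement and bile acid lists all had adjusted p = 0.525 with an estimated correlation, P450 genes adjusted p = 0.515 and cholesterol genes adjusted p = 0.48.

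Respiratory chain genes were higher on the TMM scale, but by less than the hepatocyte lists. In complex I, which takes electrons from NADH, 24 of 29 genes rose and none fell (24 adjusted over the list alone; camera adjusted p = 1.38e-07, and adjusted p = 0.525 with an estimated correlation), with a median of 0.79 that turned to -0.05 with library totals. Of that list's genes Ndufa6 rose by 1.62 and Ndufb9 by 1.10, the latter not passing with library totals (0.26, adjusted p = 0.17). The mitochondrially encoded complex I subunit Mt-nd6, which belongs to a separate list given below, rose by 1.54. Complexes II and III had 11 of 14 genes higher (12 adjusted over the list alone; median 0.64, or -0.19 with library totals), cytochrome c oxidase 8 of 15 (8 adjusted over the list alone; median 0.57, or -0.27 with library totals) and ATP synthase 11 of 15 (12 adjusted over the list alone; median 0.72, or -0.11 with library totals). Camera called these 3 lists at adjusted p = 0.00024, 0.0117 and 0.000382, against adjusted p = 0.525, 0.566 and 0.541 with an estimated correlation, and with library totals it called none of the 3. Of 13 genes encoded in mitochondrial DNA 12 rose (13 adjusted over the list alone; median 1.11, and 0.27 with library totals; camera adjusted p = 0.00049, and adjusted p = 0.525 with an estimated correlation). In the citric acid cycle list 9 of 18 genes rose and 1 fell (9 and 2 adjusted over the list alone), without a camera call (adjusted p = 0.0869; median 0.46, turning to -0.38 with library totals). Fry called that list higher (adjusted p = 0.0219).

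Cell division genes of the fixed list fell together. All 28 tested genes of that list were lower in GZM (28 adjusted over the list alone), with a median of -2.03, or a 4.09-fold fall, and camera adjusted p = 1.97e-10 (adjusted p = 0.525 with an estimated correlation). Mki67, a marker of cycling cells, fell by 2.06, the replication helicase gene Mcm3 by 1.98 and ribonucleotide reductase Rrm2 by 3.27. Among the GM libraries the list's level, as mean log2 CPM relative to the mean of the 6 libraries, was 1.12, 1.62 and 0.19, and the hepatocyte list's level was -1.61, -2.11 and -0.27 in the same order, so GM 3 held the smallest difference from GZM on both.

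Part of the T-cell, cytotoxic and MHC class II genes fell in GZM, unevenly between its libraries. The T-cell coreceptor gene Cd8a was 4.59-fold lower, at 37.3 ± 27.7 CPM against 170.9 ± 59.6 (SD, n = 3 each; log2 fold change -2.20 ± 0.51 SE, adjusted p = 0.0113). Only 4 of 21 T-cell genes fell (4 adjusted over the list alone), no larger a share than the 3104 of all 14298 tested genes, Cd28 by 2.10 and the costimulator Icos by 1.82 among them, at a list median of -1.05 (camera adjusted p = 0.00217, adjusted p = 0.649 with an estimated correlation, and 0.116 with library totals). Relative to the mean of the 6 libraries the T-cell list stood at 0.74 in GZM 1, within the GM range of 0.29 to 1.21, and at -1.31 and -1.54 in GZM 2 and GZM 3. Among cytotoxic and natural killer genes 7 of 18 fell (7 adjusted over the list alone; median -1.54; camera adjusted p = 0.00053, and adjusted p = 0.594 with an estimated correlation), with the activating receptor Klrk1 lower by 2.13 on the log2 scale, from 48.0 CPM in GM. This list too stood within the GM range (0.16 to 1.51) in GZM 1, at 0.34, and below it in GZM 2 (-1.42) and GZM 3 (-1.29). Granzyme B (Gzmb) was near the detection limit, with 84 counts in the GM libraries and 12 in the GZM libraries, and did not pass in the main test (-1.85 ± 0.74, adjusted p = 0.0742). It passed as lower in 11 of 22 other settings, most of them scaled to library totals (-2.62 in edgeR, adjusted p = 0.00994), which lowers most genes. With TMM factors it passed only without GZM 1 (-2.92, adjusted p = 0.0331) and without both GM 3 and GZM 1 (-2.31, adjusted p = 0.0298). Pdcd1, with 1 count in all 6 libraries, was not tested. MHC class II genes fell in 5 of 13 cases (9 adjusted over the list alone; median -1.43; camera adjusted p = 0.00139, and adjusted p = 0.594 with an estimated correlation), including their master regulator Ciita, by 2.27. Targets of interferon gamma were lower in all 3 GZM libraries than in any GM library as a list mean. Of 20, 13 fell and 1 rose (13 and 1 adjusted over the list alone; median -1.05; camera adjusted p = 0.000726, and adjusted p = 0.515 with an estimated correlation). The transcription factor Irf1 fell by 1.28 and the guanylate-binding protein gene Gbp2 by 2.42, and Ubd, named after its values were seen, rose by 1.64. Cd274 (ENSRNOG00000016112), which encodes the checkpoint ligand PD-L1, was 3.84-fold lower at 7.99 ± 1.31 CPM against 30.8 ± 3.64 (log2 fold change -1.94 ± 0.20 SE, adjusted p = 0.00192). Over 16 checkpoint genes 3 fell and 1 rose (2 and 1 adjusted over the list alone), with no camera call (adjusted p = 0.0618, median -0.86), and Ido1 fell by 3.50 while Lgals9 rose by 2.15.

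**Figure D3:**
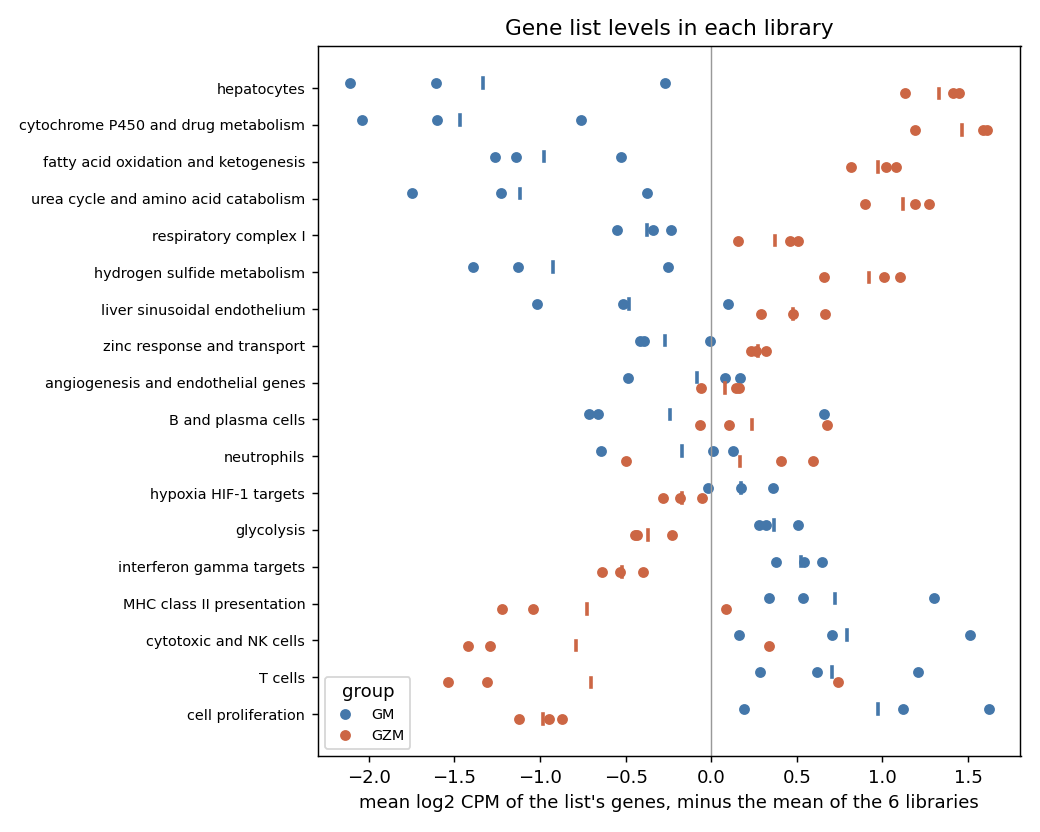
Level of 18 gene lists in each library, as the mean log2 CPM of the list's genes minus the mean of the 6 libraries; points are libraries (GM blue, GZM orange) and vertical bars are group means (n = 3). Hepatocyte and proliferation lists separate the groups in opposite directions, and T-cell genes in GZM 1 (0.74) lie within the GM range while GZM 2 and GZM 3 lie at -1.31 and -1.54; the axis is TMM-scaled, and the median fold change of complex I turns to -0.05 and that of zinc genes to -0.23 with library totals.

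Macrophage genes split. In the list of macrophages and Kupffer cells 7 of 16 genes fell and 3 rose, with the same numbers adjusted over the list alone and no camera call (adjusted p = 0.234, median -0.70). Lyz2, the lysozyme of macrophages and other myeloid cells, fell by 1.93. The 3 that rose are typical of the liver's resident macrophages: Clec4f by 2.28, and, named after their values were seen, Vsig4 by 1.73 and Cd5l by 1.83. No list of resident macrophage genes alone was tested, so these 3 do not show that such genes rose as a group. Vsig4 lost its call without GM 1 (adjusted p = 0.0794), GZM 2 (0.0544) or GZM 3 (0.0602), and Cd5l without any 1 library other than GM 3 (adjusted p from 0.0597 to 0.098). Of the genes of alternatively activated macrophages, Cd163 fell by 1.14, a call lost without GZM 1 (adjusted p = 0.053), GZM 2 (0.0758) or GZM 3 (0.0518), and Gpnmb by 1.63, a call lost without GZM 2 (0.0503). Genes of classically activated macrophages fell in 7 of 14 cases and rose in 1 (7 and 1 adjusted over the list alone; median -0.85; camera adjusted p = 0.0174, adjusted p = 0.515 with an estimated correlation, and 0.116 with library totals), with Nos2 lower by 2.35 and the chemokine Cxcl10 by 1.97 on the log2 scale, and Il1a higher by 1.54. Sinusoidal endothelial genes rose in 5 of 13 cases and none fell (5 adjusted over the list alone; median 0.80, and 0.01 with library totals; camera adjusted p = 0.0144, and adjusted p = 0.594 with an estimated correlation), with Gpr182 higher by 1.67 and the hyaluronan receptor Lyve1 by 1.57. B and plasma cell genes had no call (2 of 13 rose and 1 fell, 1 and 1 adjusted over the list alone; camera adjusted p = 0.299; median 0.47, turning to -0.29 with library totals). The gene that fell was Fcrla, by 2.93 (edgeR adjusted p = 0.00319). Those that rose, Blk and Derl3, had only 67 and 27 counts in GM.

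Most genes with the widest changes were scarce in one group, Cyp4a2 (21.6-fold higher, at 65.3 CPM in GM and 1408 in GZM) being an exception. Largest among the rises was Ltc4s, leukotriene C4 synthase, 82.2-fold higher at 54.5 ± 8.98 CPM against 0.673 ± 0.505 (log2 fold change 6.36 ± 0.46 SE, adjusted p = 0.00164). Tspo2 (5.90), Vxn (5.32), Cbln3 (5.17), Plppr1 (4.86), Prss32 (4.80), Retnlg (4.67), Gpa33 (4.63), Gnat3 (4.53) and Lrtm2 (4.47) followed on the log2 scale. Mup4, with 3 counts in GM and 51 in GZM, had a ratio of 32.5 (95% counting interval 10.5 to 162.8). Of the falls, Magel2, Mkx and Otud7a had 102, 94 and 89 counts in GM and none in GZM, which makes them at least 17.8-fold, 16.4-fold and 15.5-fold lower against a floor of 3 counts over the group. Igf2bp1, an RNA-binding protein of fetal tissues and tumours, was 42.3-fold lower (adjusted p = 0.0026), going from 15.6 ± 10.5 to 0.363 ± 0.345 CPM. Scn11a had 255 counts in GM and 1 in GZM, a ratio of 133.4 (95% counting interval 23.7 to 5289), and Bend4 had 185 and 2, a ratio of 48.4 (13.2 to 402.5). Pcdh19, Magea11, Odf3l1, Dlx4, Pax3 and Nkx2-5 each had 1 count in GZM and 154, 157, 121, 117, 108 and 97 in GM. Their GM-to-GZM ratios were 80.6 (14.2 to 3202), 82.1 (14.5 to 3264), 63.3 (11.1 to 2520), 61.2 (10.8 to 2438), 56.5 (9.93 to 2252) and 50.7 (8.89 to 2025). These intervals and floors cover counting error only.

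Gene positions are those of the deposited table. The submitters' processing notes name mRatBN7.2, but the table's chromosome 1 runs to 282724300, past the end of chromosome 1 in that build, so the build of the positions is not settled. Of the 53 lists 31 were called by camera with a preset correlation, 21 higher and 10 lower, and none with the correlation estimated for each list (lowest adjusted p = 0.48 with an estimated correlation). Limma's fry, which does not compare a list with other genes, called 25, 21 higher and 4 lower. Its adjusted p was 0.149 for T-cell, 0.0693 for cytotoxic, 0.0771 for MHC class II, 0.084 for sinusoidal endothelial, 0.131 for pericyte, 0.117 for alternatively activated macrophage, 0.0941 for dendritic cell and also 0.0941 for pericentral genes, the 8 lists that camera called and fry did not.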

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

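The settings with library totals, with median-of-ratios factors in edgeR, with limma at pseudocount 1, and without both GM 3 and GZM 1 were chosen after seeing the data. Deposited FPKM is scaled to library totals, so limma on it moves the median log2 fold change as library totals do (by -0.74 at pseudocount 1 against -0.84 in edgeR). The main count of 6285 genes became 9694 with limma at pseudocount 1, 9712 at 0.1, 9735 at 0.5, 9697 without a filter, 9709 without a trend, 9664 with a robust prior and 12788 with sample quality weights, whose estimation stopped before converging. It became 9828 in edgeR with library totals, and of these 4419 were called in the same direction in the main test and 11 in the opposite one. With scaling by median-of-ratios or quantiles limma called 5938 and 5891, edgeR with median-of-ratios 6202, DESeq2 6733 (with 4151 adjusted p not given) and edgeR without GM 3 and GZM 1 6998. A 2-fold minimum left 4142. Leaving out 1 library gave 3777 (without GZM 2) to 7024 genes (without GM 3).

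The labels state no pairing of samples by replicate number. Deviations of same-numbered samples from their group means correlated at -0.14, 0.16 and -0.27. With 3 libraries per group these values gave no sign of pairing but cannot exclude it. With the replicate block edgeR called 5166 genes and 32 lists, and limma on FPKM 8664 genes and 26 lists. Called lists, 31 in the main test, became 0 with an estimated correlation and 25 with fry, and 29 to 34 on leaving out 1 library. The dendritic cell list lost its call without GM 3 (adjusted p = 0.132), GZM 2 (0.112) or GZM 3 (0.0753), the alternatively activated macrophage list without GM 1 (0.0515), GM 3 (0.182) or GZM 2 (0.112), pericentral genes without GM 2 (0.0596) or GZM 1 (0.111), and the pericyte list (0.0983) and the damage signal list (0.0858) without GM 1. Over all 24 other settings the call was lost in 15 for dendritic cells, 14 for alternatively activated macrophages, 13 for damage signals, 12 each for respiratory complexes II and III and for ATP synthase, 10 each for cytochrome c oxidase (with 2 more reversed), pericytes, T cells and classically activated macrophages, 5 for pericentral, 4 for cytotoxic, 3 for MHC class II and 2 each for glycolysis and sinusoidal genes. Each other called list lost it in 1, with an estimated correlation, and mitochondrially encoded genes also reversed in 1. Of lists not called in the main test, the erythroid list was called in 17, B cells and checkpoints in 4 each, the citric acid cycle and type I interferon in 3 each, hypoxia, MHC class I and stellate cells in 2 each, and zinc, macrophages, cholangiocytes and matrix in 1 each. Among 23 other settings per gene the call was lost in 14 for Flt4, 10 each for Alb and Egfl7 9 each for Vegfa and Ndufb9, 7 each for Hbb and Cd5l, 6 for Pck2, 5 for Vsig4, 4 for Xbp1, 3 each for Lyve1 and Cd163 and 2 for Angpt2. Ubd, Pax3, Nkx2-5, Mx2, Mt-nd6, Mkx, Il1a, Gpnmb and Dlx4 lost it in 1 each. Of genes that did not pass, Ldhb passed in 13, Ldha as higher in 4 and Mt1 and Mt2A in 3 each. Gzmb passed in 11 of 22. Most settings in which Ldhb or Gzmb passed were scaled to library totals.

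Values that turned direction are log2 fold changes, medians for lists; for lists the direction is that of the list test, and the cause was not tested. Ldha was -0.21 in every limma setting on FPKM except median-of-ratios, quantile scaling (-0.0719) and quality weights (-0.12), and -0.23 with library totals. Slc30a1 was -0.57 in limma with pseudocount 1, without filter, at mean FPKM 1, with the block, without trend and with the robust prior, -0.61 at pseudocount 0.1, -0.59 at 0.5, -0.76 with quality weights and -0.60 with library totals. Mt2A was -0.0321 with library totals. With quality weights the medians were -0.86 for endothelial, -1.15 for macrophage and Kupffer, -0.59 for NRF2 and -0.58 for cholangiocyte genes. Without a filter limma gave -0.26 for cytochrome c oxidase, -0.60 for NRF2, -0.66 for p53 and -0.0472 for mesothelium. Quantile scaling gave -0.0428 for cytochrome c oxidase, -0.50 for mitochondrially encoded genes, -0.19 for NRF2, -0.00914 for p53, -0.00889 for mast cells and -0.40 for mesothelium. The p53 list was -0.66 in limma at pseudocount 1, with the block, without trend and with the robust prior, -0.71 at 0.1, -0.69 at 0.5 and -0.051 without GM 1. Fetal liver and tumour genes were -0.86 in limma at pseudocount 1, without trend and with the robust prior, -1.14 at 0.1, -0.996 at 0.5, -0.85 at mean FPKM 1 and -1.04 with library totals. Mesothelium was -0.95 in limma at pseudocount 1, without trend and with the robust prior, and 0.44 in edgeR without a filter, where pancreas, gut, muscle and fat genes were -0.31. Mast cell genes were -1.04 at pseudocount 0.1 and -0.63 at mean FPKM 1, and ranged from -0.755 (without GZM 1) to -0.0331 (without GM 3) on leaving out 1 library, with the list test's direction turning without GM 3, GZM 2 (-0.0805) or GZM 3 (-0.27). Neutrophil genes were 0.00139 in fry and ranged from -0.31 to -0.07 without GM 2, GZM 2 or GZM 3.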

Other observations

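The list tests were fixed before the data were seen, and the counts over divisions of the samples were planned before they were run. The tests that weigh the 3 patterns at the end were chosen after the results they address had been seen, and the length correction had also been run once before it was written down. The pathway tests from the table's annotation were added after seeing the data. Several fixed lists outside the main account also differed between groups. Acute phase genes rose in 15 of 18 cases and 1 fell (median 2.51; Hamp, the iron hormone hepcidin, by 2.20). Periportal hepatocyte genes rose in 12 of 15 cases (median 2.45) and pericentral ones in 5 of 13 (median 1.77, but 0.57 without GZM 1, whose list level was 1.36 against 0.21 and 0.25 in GZM 2 and GZM 3), fatty acid and triglyceride synthesis genes in 9 of 15 (median 1.20) and clock genes in 9 of 17 with 1 lower (median 0.67, -0.15 with library totals; Per2 by 2.26). In the list of damage signals and endoplasmic reticulum stress 10 of 24 rose, the stress factor gene Xbp1 by 1.42, and Anxa1 alone fell, by 1.13 (median 0.40, -0.41 with library totals). Dendritic cell genes fell in 6 of 19 cases (median -0.37; Cd80 by 2.54, Clec10a by 1.58), alternatively activated macrophage genes in 6 of 14 (median -0.73), and pericyte genes in 3 of 14 (median -0.88; Notch3 by 2.19). Camera called these 9 lists with a preset correlation and none with an estimated one (adjusted p between 0.48 and 0.649 with an estimated correlation). Of the 9 calls 5 ended on leaving out 1 library. These were dendritic cells without GM 3 (median -0.11, adjusted p = 0.132), GZM 2 (0.112) or GZM 3 (0.0753), alternatively activated macrophages without GM 1 (0.0515), GM 3 (median -0.44, adjusted p = 0.182) or GZM 2 (0.112), pericytes without GM 1 (median -0.44, adjusted p = 0.0983), damage signals without GM 1 (median 0.27, adjusted p = 0.0858), and pericentral genes without GM 2 (0.0596) or GZM 1 (0.111).

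The remaining lists had no camera call, and most held genes that moved both ways. Type I interferon genes rose in 7 of 25 cases and fell in 3 (Ifi27 higher by 2.02, Mx2 by 2.81), NRF2 targets in 5 and 5 of 16 (Osgin1 higher by 3.10, the cystine transporter Slc7a11 lower by 3.03), p53 targets in 5 and 4 of 17 (Btg2 higher by 2.04, Pmaip1 lower by 2.32), and cell death genes in 4 and 4 of 16 (Aifm2 higher by 1.51, Ripk3 lower by 1.56, Casp1 lower by 1.60). Neutrophil genes split 2 and 2 of 14, with Lcn2 (3.03) and Cxcl1 (2.53) higher and Fcnb (-1.86) and Csf3r (-1.46) lower. Of the fetal liver and tumour list 2 of 12 rose, Afp among them, and 4 fell, Gstp1 by 1.72. Matrix remodelling genes fell in 7 of 18 cases and rose in 1, stellate cell genes rose in 4 and fell in 3 of 19, cholangiocyte genes rose in 3 and fell in 1 of 14, immediate early genes rose in 5 and fell in 4 of 16, and MHC class I genes fell in 3 of 16. Erythroid genes rose in 3 of 10 cases (Hbb by 1.87, a call lost without any 1 library other than GM 3, with adjusted p from 0.0551 to 0.103), and the list, at a camera adjusted p of 0.0643, was called in 17 of 24 other settings, where adjusted p went down to 0.000196. Mast cell genes rose in 1 of 7 cases. Mesothelial genes rose in 1 of 5 cases with 2 lower, and 2 of 5 pancreas, gut, muscle and fat genes rose although their median was -0.42. Of 326 KEGG pathways in the table's own annotation, tested as an exploration, camera called 106 with the preset correlation and 0 with an estimated one, led by retinol metabolism (51 of 61 genes higher). Among them the HIF-1 signaling pathway was called lower (41 of 115 fell, 18 rose; adjusted p = 0.0295) and the citrate cycle higher (17 of 31 rose, 3 fell; adjusted p = 0.00935), both with adjusted p = 0.518 with an estimated correlation, and cell cycle genes fell in 65 of 125 cases and rose in 3.

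The 2 counts that lead the account were set against the other ways of dividing the 6 libraries into 3 and 3. The real division gave 6285 genes and the highest of the other 9 gave 0, so 1 of 10 divisions gave as many. For lists the real division gave 31 and the highest of the others 30, again 1 of 10, and the lowest of the others gave 21. With 10 divisions no share under 0.05 can be reached. Each of the other 9 divisions joined 2 libraries of one group with 1 of the other, so part of the real difference stayed between its sides. The rest widened the spread within them, so neither 0 genes nor 21 to 30 lists is a chance level. A preset camera call on its own did not tell the labelled groups from these mixed ones. The counts of changed genes differed between lists: 28 of 28 proliferation genes fell, but 4 of 21 T-cell and 3 of 14 pericyte genes, no larger a share than the 3104 of all 14298 tested genes. Genes of a list can move together, with an estimated correlation of 0.915 among proliferation genes, so such counts are not counts of separate measurements.

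The first pattern is the rise of hepatocyte genes with the fall of proliferation genes. The scaling factors alone do not account for it, since with library totals the hepatocyte median stayed at 1.69 (quartiles 1.55 and 1.88). Gene length does not account for it either, since the median was 2.51 after the length trend was removed (quartiles 2.26 and 2.65; Spearman rho of -0.108 between fold change and length across genes). A larger share of otherwise equal hepatocytes, with no other cell making these genes, would raise P450 and complement genes alike, but their log2 ratio per library was higher in GZM by 0.60 (pooled SD 0.246), without overlap. The pair was chosen after P450 genes were seen to have the highest list median (2.92, against 2.34 for complement genes). Acute phase (2.51), hepatocyte (2.44), urea cycle (2.23) and bile acid (2.17) medians lay nearer that of complement genes. Fatty acid oxidation (1.87) and cholesterol (1.47) medians lay further below it. The ratio thus shows that these lists moved apart and cannot exclude a larger share alone. What stays open is a different share of hepatocytes, alone or together with some change in them, other cells that make complement genes, and an effect of the zinc sulfide, which the tissue pieces taken could also mimic.

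The second pattern is that genes of other cell types moved apart. If hepatocyte RNA had only diluted every other cell type, proliferation and endothelial genes would have fallen alike, but their difference per library moved by -2.12 (pooled SD 0.728), without overlap. Proliferation genes mark dividing cells of any type, and the pair was chosen after the list medians were seen. The difference therefore cannot exclude dilution. Medians of T-cell (-1.05), pericyte (-0.88), macrophage (-0.70) and stellate (-0.63) genes were negative. Those of cholangiocyte (0.41), B-cell (0.47) and sinusoidal (0.80) genes were positive, and these lists were not tested against each other. A candidate source of the proliferation and Igf2bp1 transcripts is cancer cells, which can express genes otherwise limited to the germline. A list of 55 germline genes was written after 5 of them (Magel2, Magea9, Magea11, Nlrp4 and Tex19.1) had been seen to fall, so these were left out of its test. Of the 9 others tested, 6 fell and 0 rose, with a median of -2.92 against -2.03 for proliferation genes and a lower quartile of -3.16, but the upper quartile was 0.46, so the test did not settle whether fewer such cells were present in GZM.

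The third pattern is the lower list medians of cytotoxic, T-cell and MHC class II genes, although only 4 of 21 T-cell genes fell and fry called none of these lists. Fewer leukocytes of every kind would lower cytotoxic and B-cell genes alike, but their difference per library moved by -2.06 (pooled SD 0.47), without overlap. The B-cell list is a weak reference. Its called risers, Blk and Derl3, had 67 and 27 counts in GM, while Fcrla, with 2901, fell by 2.93. The difference thus shows that the 2 lists moved apart and cannot exclude fewer leukocytes. The cytotoxic median stayed at -1.56 after the length trend was removed (quartiles -1.91 and -1). The shared leukocyte gene Ptprc, chosen after its values were seen, fell by 1.36. A different mix of leukocytes stays open, as do fewer leukocytes of every kind and an effect of the zinc sulfide. In GZM 1 the mean levels of the T-cell (0.74) and cytotoxic (0.34) lists lay within the GM range. Cd8a, Cd28, Icos and Klrk1 were lower in all 3 GZM libraries than in any GM library. However, Cd28, Icos and Klrk1 were named for their small p in these data, and 58.1% of all tested genes did not overlap. These genes therefore do not show that the lists fell in GZM 1.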
